A study of Arabidopsis thaliana with 9 samples.

How the data were processed

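The series measured mRNA in whole rosettes of Arabidopsis thaliana wild type (Col-0) and the mutants pdx3-3 and pdx3-4, with 3 libraries per genotype. Per the labels, rosettes were frozen and ground, RNA was extracted with a PureLink kit, polyA RNA was selected and libraries were made with an Illumina TruSeq stranded kit, and all 9 libraries were pooled for sequencing. The deposited values are whole-number counts per gene locus, 1 column per library, not normalized. FastQC, TopHat2 (version 2) and the build TAIR10 are named per the submitters' processing notes. The counting tool, its strand setting and its treatment of reads that map to several places were not given in the sources used here, so near-identical copies, overlapping genes and antisense partners are uncertain.

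Samples were assigned to groups by the genotype in their labels. Counts summed to 15912737 to 21938941 per library. Wilson 95% intervals of shares cover counting error only, as reads are not independent molecules; a count of 0 allows up to 3 counts. Replicate libraries of a genotype differed by more than sampling noise, with chi-square per degree of freedom of 5.44 to 26.2, so none was treated as a repeat of another. Gene names and coordinates were taken from the TAIR10.1 reference, by locus ID: 32835 of 33602 IDs matched, 488 nuclear IDs did not, and 279 were organellar. The files carry no coordinates. Symbols are printed as the reference gives them, with other names once where lists use them.

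Genes were filtered with filterByExpr, leaving 18783. Counts were scaled by TMM factors (0.949 to 1.03) and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, in a fit of all 9 libraries with genotype as the only term, which leaves 6 residual degrees of freedom. The common dispersion was 0.0118, a biological coefficient of variation of 0.109. All adjusted p-values for genes are Benjamini-Hochberg values from this edgeR test, called under 0.05. Comparisons were pdx3-3 against wild type, pdx3-4 against wild type, pdx3-3 against pdx3-4, and the mean of both alleles against wild type. The SE of a log2 fold change is its size over the square root of the test's F statistic. Log2 CPM in the list tests had a prior count of 2. With 3 libraries against 3, a permutation test on a single gene could not go below 0.10.

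The comparisons, the tests, the 30 gene lists and the rule for named genes were chosen before the data were examined. The lists hold 437 members, all found in the files, 4 of them in more than 1 list, and cover ER chaperones, NLR immune receptors, PLP-dependent enzymes of amino acid metabolism, ammonium uptake and assimilation, auxin response, cell division, circadian clock, cold and abscisic acid response, flavonoid and anthocyanin synthesis, flowering and floral organ markers, glucosinolate synthesis and breakdown, guard cell and stomatal lineage markers, heat shock, iron deficiency and storage, jasmonate and ethylene response, leaf senescence, nitrate uptake and reduction, nitrate-responsive genes, oxidative stress, pattern-triggered immunity and camalexin, phloem markers, phosphate starvation, photorespiration, photosynthesis, nuclear genes, root cell markers, salicylic acid defence, shoot meristem markers, sulfur assimilation and deficiency, trichome markers, vitamin B6 metabolism. Lists with at least 3 tested members were tested with camera of limma 3.58.1 at an inter-gene correlation of 0.01, again with the correlation estimated per list, and with fry, which asks whether members move on balance 1 way. Camera sets the members against all other tested genes and fry does not. Where many genes change, a list that passes fry is not shown to stand out from them. Named genes are PDX3 and the vitamin B6 list; for each allele against wild type, and between the alleles, the 6 higher and 6 lower genes with the largest fold among those called, with a mean of at least 5 CPM in the higher group and no overlap of libraries; and up to 4 members of each list with the smallest adjusted p for both alleles. Genes outside this rule are said to be chosen after their values were seen.

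The pipeline was tested on simulated counts with 200 genes changed, of which it recovered 50.8%, 82.1% and 92.4% at 1.5, 2 and 4-fold for pdx3-3 against wild type (18659 genes tested), 38.8%, 77.6% and 98.5% for pdx3-4 (18644), 41.8%, 80.6% and 92.4% between alleles (18654) and 61.2%, 86.6% and 95.5% for both alleles (18647). False calls were 8 of 158, 12 of 155, 12 of 155 and 17 of 179. In the data 1157 to 8134 genes were called per comparison, far more than were simulated, so these rates can differ there. Overlap of calls was compared with 20 simulations of unchanged groups against shared wild-type libraries.

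Alternatives were other size factors (median-of-ratios, upper-quartile, library size only), no filter or at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, robust quasi-likelihood, organellar genes left out, the replicate number as a block, only the groups compared, stricter thresholds and each library left out. Added after seeing the data were pdx3-3 libraries 1 and 2 left out together, because of their organellar and ribosomal RNA shares, wild type 1 and pdx3-4 1 left out together, because each had the highest PR1 level of its genotype, organellar with ribosomal RNA genes left out, and PDX3 left out of the vitamin B6 list. The removal by PR1 level kept pdx3-3 2, which also had the highest PR1 level of its genotype. That removal can therefore favour higher defence genes in pdx3-3. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.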

Results

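Transcript abundance was measured by polyA-selected mRNA sequencing in whole rosettes of Arabidopsis thaliana at 21 days of age, grown on soil with 16 hours of light and 8 hours of dark. The series held 9 libraries: 3 of wild type (ecotype Col-0), 3 of pdx3-3 and 3 of pdx3-4, which are insertion lines in PDX3, the gene for the oxidase that makes pyridoxal 5'-phosphate (PLP, the cofactor form of vitamin B6) from pyridoxine 5'-phosphate and pyridoxamine 5'-phosphate. The labels call the samples of a genotype biological replicates. Total counts were 19427283, 21938941 and 18689726 in the wild-type libraries, 15912737, 20185321 and 20973958 in pdx3-3 and 21312901, 20802960 and 20754721 in pdx3-4. Of 33602 genes in the files, 18783 passed the filter on low counts. The 10 most abundant genes took 10.6% to 13.4% of the counts of a library. Among the 500 most variable genes, the leading principal component held 77.3% of the variance and the next 11.5%. The chloroplast share of the counts was 0.536% (Wilson 95% interval 0.532 to 0.539) in pdx3-3 library 1 and 0.175% (Wilson 95% interval 0.173 to 0.176) in pdx3-3 library 2, against 0.0162% to 0.0532% in every other library. The same libraries held more ribosomal RNA counts, 0.774% (Wilson 95% interval 0.770 to 0.778) and 0.242% (Wilson 95% interval 0.240 to 0.244), against 0.0120% to 0.0608% elsewhere.

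PDX3 transcript was reduced in both mutants, more so in pdx3-3. PDX3 (AT5G49970, named PPOX in the reference, chromosome 5, 20329103 to 20333172 in TAIR10.1) had 88.2 ± 8.51 CPM (counts scaled to library size, mean ± SD, n = 3) in wild type, 9.29 ± 1.22 in pdx3-3 and 45.4 ± 4.30 in pdx3-4. In pdx3-3 (log2 −3.25, SE 0.12, adjusted p = 9.54e-08) and pdx3-4 (log2 −0.96, SE 0.11, adjusted p = 4.36e-05) all 3 libraries of each mutant lay below every wild-type library, and the alleles differed from each other (log2 −2.29, SE 0.12, adjusted p = 8.56e-06). The position of the insertions and of the counted reads along the gene was not analysed here, so the counts do not tell full-length from partial transcript.

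**Figure D1:**
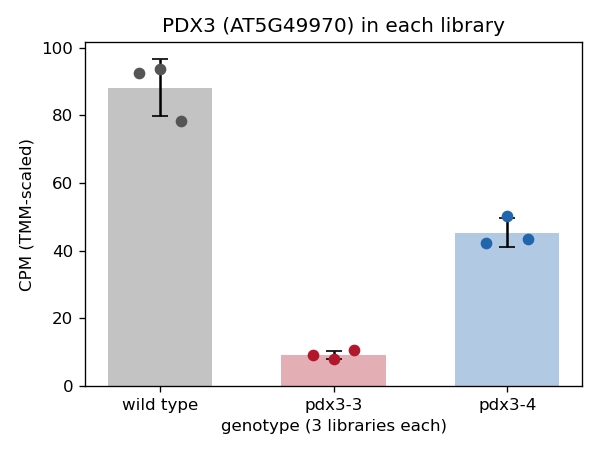
PDX3 transcript abundance in CPM (TMM-scaled, linear axis from 0) for wild type, pdx3-3 and pdx3-4. Points are the 3 libraries of each genotype, bars the mean and error bars the SD: 88.2 ± 8.51, 9.29 ± 1.22 and 45.4 ± 4.30 CPM, with no overlap between genotypes.

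Transcripts of the PLP synthase genes PDX1.1 and PDX1.3 were lower in both mutants. PDX1.1 (AT2G38230, log2 −0.49, SE 0.080, adjusted p = 0.000801) and RSR4 (also PDX1.3, AT5G01410, log2 −0.50, SE 0.077, adjusted p = 0.000485) encode subunits of the synthase that makes PLP without PDX3, and both fell in pdx3-3. In pdx3-4, PDX1.1 fell by 0.24 on the log2 scale (SE 0.080, adjusted p = 0.0330) and RSR4 by 0.46 (SE 0.077, adjusted p = 0.000754). PDX1.2, the non-catalytic paralog of that synthase, rose in pdx3-3 (AT3G16050, log2 0.76, SE 0.14, adjusted p = 0.00135) and was not called in pdx3-4 (log2 0.12, adjusted p = 0.541), with log2 0.64 between the alleles (adjusted p = 0.0196). PLR1 (AT5G53580), a pyridoxal reductase, had log2 −0.23 in pdx3-3 (adjusted p = 0.0553) and −0.24 in pdx3-4 (adjusted p = 0.0491). PDX2 (AT5G60540), the glutaminase subunit, and SOS4 (AT5G37850), the salvage kinase, were not called in either allele, with log2 −0.051 and −0.066 in pdx3-3 and −0.038 and 0.011 in pdx3-4 (adjusted p = 0.670, 0.441, 0.752 and 0.910). For both alleles together, the vitamin B6 list had 1 higher, 4 lower and 2 not called of 7 tested members (1 and 4 adjusted over the list alone), a median log2 of −0.24. Camera on vitamin B6 metabolism gave adjusted p = 0.108, or adjusted p = 0.510 with an estimated correlation. With fry it passed (adjusted p = 0.000461), but PDX3 itself is a member. Without PDX3, a check chosen after seeing the data, the list had 1 higher and 3 lower of 6 (1 and 3 adjusted over the list alone), a median log2 of −0.14 and adjusted p = 0.352 by camera, 0.692 with an estimated correlation and 0.0216 by fry, the last lost without wild type 1 or 2, pdx3-3 1 or pdx3-4 2 (0.0510 to 0.0969). The PDX1.1 call in pdx3-4 was lost without wild type 2, pdx3-3 2 or any of the pdx3-4 libraries (adjusted p = 0.0508 to 0.116), the PLR1 call in pdx3-4 when any single library other than wild type 3 was left out (0.0641 to 0.180), and the PDX1.2 difference between alleles without pdx3-3 2 or any pdx3-4 library (0.0591 to 0.0802), while PLR1 passed in pdx3-3 without wild type 3 (0.00416) and PDX1.1 between alleles without wild type 2 (0.0454). Against wild type, log2 for both alleles together was −2.10 for PDX3, −0.48 for RSR4, −0.36 for PDX1.1 and 0.44 for PDX1.2 (adjusted p = 1.94e-07, 0.000160, 0.00143 and 0.0132), the last of which was lost without wild type 2 (0.0631) or with upper-quartile factors (0.0521). The PDX1.1 and PLR1 calls in pdx3-4 were also lost with library size alone (0.05765 and 0.0770) and with only these groups fitted (0.0598 and 0.0844), and PLR1 with no filter (0.05785) and limma-voom (0.0546). With upper-quartile factors PLR1 and SOS4 passed in pdx3-3 (0.00394 and 0.0276). The list with PDX3 passed camera without wild type 3 (adjusted p = 0.03945 for both alleles, 0.0302 for pdx3-3 and 0.0451 for pdx3-4), but not with PDX3 left out as well (0.1325 to 0.161).

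With both alleles set against wild type, which tests the mean of the alleles and so can be moved by 1 of them, defence genes rose, and salicylic acid defence had the highest median among the tested lists. Of 33 tested genes of salicylic acid defence, 26 rose, 1 fell and 6 were not called (28 and 1 adjusted over the list alone). The list had a median log2 of 2.22. Camera on salicylic acid defence gave adjusted p = 9.25e-13, or adjusted p = 0.249 with an estimated correlation. PBS3 (AT5G13320, log2 2.4, SE 0.096, adjusted p = 1.35e-07), which conjugates glutamate to isochorismate in salicylic acid synthesis, EDS5 (AT4G39030, log2 2.07, SE 0.10, adjusted p = 3.47e-07), the plastid exporter of that precursor, SARD1 (AT1G73805, log2 3.68, SE 0.19, adjusted p = 3.47e-07), a transcription factor of the pathway, and WRKY18 (AT4G31800, log2 4.36, SE 0.22, adjusted p = 3.66e-07) had the smallest adjusted p of the list. Among genes of pattern-triggered immunity and camalexin, 16 of 23 rose and 0 fell (17 and 0 adjusted over the list alone), with a median log2 of 1.5. Camera on pattern-triggered immunity gave adjusted p = 5.27e-08, or adjusted p = 0.249 with an estimated correlation. MPK3 (AT3G45640, log2 2.02, SE 0.15, adjusted p = 2.64e-06) and MPK11 (AT1G01560, log2 3.3), immune MAP kinases, CYP81F2 (AT5G57220, log2 3.78), an indole glucosinolate hydroxylase, and PHI-1 (AT1G35140, log2 5.83) were its leading members. NLR immune receptors rose in 15 of 16 tested genes and fell in 0 (15 and 0 adjusted over the list alone, median log2 0.85). Camera on NLR immune receptors gave adjusted p = 1.33e-07, or adjusted p = 0.358 with an estimated correlation. The helper receptors ADR1-L2 (AT5G04720, log2 1.74, SE 0.094, adjusted p = 4.35e-07), ADR1 (AT1G33560, log2 1.82) and ADR1-L1 (AT4G33300, log2 1.60) led this list, followed by RPM1 (AT3G07040, log2 1.23). In the jasmonate and ethylene list, 15 of 25 genes rose and 2 fell (16 and 2 adjusted over the list alone), at a median log2 of 0.93. Camera on jasmonate and ethylene genes gave adjusted p = 0.000144, or adjusted p = 0.249 with an estimated correlation. They included the lipoxygenase LOX4 (AT1G72520, log2 4.00, SE 0.30, adjusted p = 2.52e-06) and the jasmonate repressors JAZ1 (AT1G19180, log2 2.59), JAZ7 (AT2G34600, log2 5.32) and JAZ5 (AT1G17380, log2 2.34).

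Oxidative stress, ER chaperone and sulfur genes rose as well. In the oxidative stress list, 10 of 15 tested genes rose and 1 fell (11 and 1 adjusted over the list alone), with a median log2 of 0.99. Camera on oxidative stress gave adjusted p = 0.000195, or adjusted p = 0.249 with an estimated correlation. BCS1 (also OM66, AT3G50930, log2 4.36, SE 0.17, adjusted p = 1.07e-07), a mitochondrial outer membrane ATPase, STZ (also ZAT10, AT1G27730, log2 2.65), a zinc finger repressor, and the glutathione transferases GSTF6 (AT1G02930, log2 1.88) and GSTF8 (AT2G47730, log2 0.99) led it. Each of the 8 ER chaperones rose (8 adjusted over the list alone, median log2 0.47). Camera on ER chaperones gave adjusted p = 0.000195, or adjusted p = 0.358 with an estimated correlation. Examples were BIP3 (AT1G09080, log2 3.18, SE 0.25, adjusted p = 3.41e-06), CRT3 (AT1G08450, log2 1.02), PDIL1-1 (AT1G21750, log2 0.69) and BIP2 (AT5G42020, log2 0.52), which serve protein folding in the secretory pathway. Sulfur assimilation and deficiency genes rose in 6 of 6 cases (6 adjusted over the list alone, median log2 1.05). Camera on sulfur genes gave adjusted p = 0.000226, or adjusted p = 0.249 with an estimated correlation. These were led by the adenylylsulfate reductases APR3 (AT4G21990, log2 1.12, SE 0.086, adjusted p = 3.03e-06), APR2 (AT1G62180, log2 0.66) and APR1 (AT4G04610, log2 0.99), and by the sulfur deficiency gene ATSDI1 (also SDI1, AT5G48850, log2 2.77). How reads that GSTF6 shares with its near-identical neighbour GSTF7 were counted was not given in the sources used here.

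Genes of photosynthesis, photorespiration and flavonoid synthesis fell. Of 32 nuclear photosynthesis genes, 31 fell and 0 rose (31 and 0 adjusted over the list alone), by a median log2 of −0.33. Camera on nuclear photosynthesis genes gave adjusted p = 2.19e-09, or adjusted p = 0.358 with an estimated correlation. RBCS2B (AT5G38420, log2 −0.88, SE 0.078, adjusted p = 8.02e-06) and RBCS1B (AT5G38430, log2 −0.94), small subunits of Rubisco, NPQ4 (also PSBS, AT1G44575, log2 −0.66), the sensor of energy-dependent quenching, and DRT112 (AT1G20340, log2 −0.40), a plastocyanin, were the leading members, the RBCS genes and LHCB1 genes being near-identical copies whose counts are uncertain. All 14 photorespiration genes fell (14 adjusted over the list alone, median log2 −0.41). Camera on photorespiration gave adjusted p = 1.44e-05, or adjusted p = 0.358 with an estimated correlation. They included DiT1 (AT5G12860, log2 −0.69, SE 0.072, adjusted p = 2.33e-05), a plastid dicarboxylate transporter, AT1G11860 (also GLDT, log2 −0.63), the T-protein of glycine decarboxylase, CAT2 (AT4G35090, log2 −0.73), the leaf peroxisomal catalase, and GOX1 (AT3G14420, log2 −0.48), a glycolate oxidase. In flavonoid and anthocyanin synthesis, 14 of 16 genes fell and 0 rose (14 and 0 adjusted over the list alone), at a median log2 of −0.91. Camera on flavonoid genes gave adjusted p = 3.62e-05, or adjusted p = 0.358 with an estimated correlation. TT5 (also CHI, AT3G55120, log2 −0.74, SE 0.092, adjusted p = 8.25e-05), chalcone isomerase, F3H (AT3G51240, log2 −0.69), flavanone hydroxylase, GSTF12 (also TT19, AT5G17220, log2 −1.56), needed for vacuolar anthocyanin uptake, and AT4G14090 (also UGT75C1, log2 −1.74), an anthocyanin glucosyltransferase, were among them. Glucosinolate genes were mixed: 2 rose, 11 fell and 7 were not called of 20 (2 and 13 adjusted over the list alone), with a median log2 of −0.53. Camera on glucosinolate genes gave adjusted p = 0.0203, or adjusted p = 0.687 with an estimated correlation. MYB51 (AT1G18570, log2 2.99, SE 0.16, adjusted p = 4.86e-07) rose while its fellow regulator of indolic glucosinolates MYB34 (AT5G60890, log2 −2.4) fell, as did the aliphatic regulator MYB28 (AT5G61420, log2 −1.56) and the glucosyltransferase gene AT2G31790 (also UGT74C1, log2 −0.79). That list was not past the threshold without wild type 3 (adjusted p = 0.134) or with upper-quartile factors (0.111), nor with fry (0.0671).

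Nitrogen genes changed in both directions, and none of their lists passed camera as a set, while fry passed ammonium uptake and assimilation, nitrate-responsive genes and PLP-dependent enzymes (adjusted p = 7.40e-05, 0.00691 and 0.0116) but not nitrate uptake and reduction (adjusted p = 0.160). In nitrate uptake and reduction, 3 rose, 4 fell and 5 were not called (4 and 4 adjusted over the list alone; median log2 0.26). Camera on nitrate uptake and reduction gave adjusted p = 0.753, or adjusted p = 0.813 with an estimated correlation. Nitrate reductase NIA1 (AT1G77760, log2 −0.80, SE 0.072, adjusted p = 8.84e-06) and nitrite reductase NIR1 (AT2G15620, log2 −0.53) fell, whereas WR3 (also NRT3.1, AT5G50200, log2 1.22), a partner of high-affinity nitrate transporters, and CLC-A (AT5G40890, log2 0.73), the vacuolar nitrate antiporter, rose. The nitrate-responsive list had 6 higher, 5 lower and 5 not called of 16 tested members (6 and 6 adjusted over the list alone), with a median log2 of 0.045 that turned to −0.076 with upper-quartile factors. Camera on nitrate-responsive genes gave adjusted p = 0.533, or adjusted p = 0.813 with an estimated correlation. BT2 (AT3G48360, log2 4.12, SE 0.24, adjusted p = 5.89e-07) and BT1 (AT5G63160, log2 2.12), BTB/TAZ scaffold proteins, HB1 (AT2G16060, log2 1.55), a hemoglobin, and AT1G68670 (also HHO2, log2 0.55), a nitrate-induced repressor, rose. For ammonium uptake and assimilation, 6 rose, 4 fell and 7 were not called (6 and 4 adjusted over the list alone). Camera on ammonium uptake and assimilation gave adjusted p = 0.404, or adjusted p = 0.527 with an estimated correlation. Its median log2 of −0.015 turned to 0.038 with library size alone, against a mean of 0.40 and a test pointing up. ASN1 (AT3G47340, log2 3.25, SE 0.24, adjusted p = 2.15e-06), asparagine synthetase, GDH1 (AT5G18170, log2 0.95), glutamate dehydrogenase, GSR 1 (also GLN1-1, AT5G37600, log2 1.60), a cytosolic glutamine synthetase, and AMT2 (also AMT2-1, AT2G38290, log2 1.47), an ammonium transporter, rose. PLP-dependent enzymes of amino acid metabolism had 7 higher, 18 lower and 9 not called of 34 tested members (7 and 18 adjusted over the list alone). Camera on PLP-dependent enzymes gave adjusted p = 0.129, or adjusted p = 0.510 with an estimated correlation. Their median log2 was −0.25 and their mean 0.039, the test pointing down. ALAAT2 (AT1G72330, log2 1.39, SE 0.11, adjusted p = 3.10e-06), an alanine aminotransferase, and GAD (also GAD1, AT5G17330, log2 2.58), glutamate decarboxylase, rose, and MTO1 (also CGS1, AT3G01120, log2 −0.64), cystathionine gamma-synthase, and ADC1 (AT2G16500, log2 −0.65), arginine decarboxylase, fell.

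The clock genes that were called parted by time of day. The list had 5 higher, 8 lower and 1 not called of 14 tested members (5 and 8 adjusted over the list alone), a median log2 of −0.64 that turned to 0.092 with no filter. Camera on circadian clock gave adjusted p = 0.232, or adjusted p = 0.634 with an estimated correlation. With fry the clock list passed (adjusted p = 0.000562). LHY (AT1G01060, log2 −1.09, SE 0.059, adjusted p = 4.42e-07), CCA1 (AT2G46830, log2 −0.83) and RVE8 (AT3G09600, log2 −0.89), MYB factors that peak around dawn, and CDF1 (AT5G62430, log2 −0.99) fell. Chosen after their values were seen, the evening genes TOC1 (AT5G61380, log2 1.14), PRR5 (AT5G24470, log2 0.97), GI (AT1G22770, log2 0.55), ELF3 (AT2G25930, log2 0.70) and PCL1 (also LUX, AT3G46640, log2 0.95) rose and PRR7 (AT5G02810, log2 0.093, adjusted p = 0.206) was not called. The hour of harvest was not given in the sources used here.

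**Figure D2:**
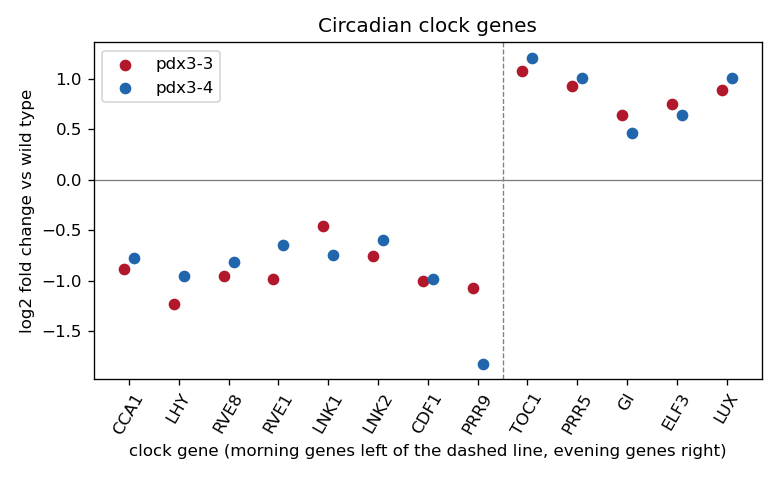
Log2 fold change against wild type (vertical axis) of clock genes (horizontal axis) in pdx3-3 and pdx3-4, 1 point per gene and allele from 3 against 3 libraries. PRR7, which was not called, was given no phase and is not shown. The 8 morning genes shown lie below 0 in both alleles and the 5 evening genes above 0.

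Among cell type markers, those of guard cells and the stomatal lineage fell in 6 of 6 tested genes (6 adjusted over the list alone, median log2 −1.01). Camera on guard cell markers gave adjusted p = 0.000195, or adjusted p = 0.249 with an estimated correlation. MYB60 (AT1G08810, log2 −1.42, SE 0.11, adjusted p = 2.51e-06) and KAT1 (AT5G46240, log2 −0.79), expressed in guard cells, and SPCH (AT5G53210, log2 −1.18) and FMA (also FAMA, AT3G24140, log2 −0.80), factors of stomatal development, were among them. Phloem markers APL (AT1G79430, log2 −0.63, SE 0.13, adjusted p = 0.00292) and SUC2 (AT1G22710, log2 −0.46) fell (2 adjusted over the list alone), and the meristem markers KNAT1 (AT4G08150, log2 1.66, SE 0.34, adjusted p = 0.00232) and STM (AT1G62360, log2 1.3) rose (2 adjusted over the list alone), with 2 tested members in each list, too few for a set test. KNAT1 and STM were both called in pdx3-3 and not called in pdx3-4 (adjusted p = 0.134 and 0.197). In the direct test between the alleles only KNAT1 was called, while adjusted over the list alone 2 of 2 were higher in pdx3-3. An allele difference of STM thus depends on the adjustment, and its rise is not shown to be confined to pdx3-3. KNAT1 had CPM of 0.529 ± 0.141 in wild type, 3.08 ± 1.21 in pdx3-3 and 0.927 ± 0.0418 in pdx3-4. Of 3 trichome markers, TRY (AT5G53200, log2 −1.89, SE 0.20, adjusted p = 2.50e-05) fell while MYB0 (also GL1, AT3G27920, log2 −0.092, adjusted p = 0.80) and GL2 (AT1G79840, log2 0.090, adjusted p = 0.824) were not called, GL2 turning to −0.023 with upper-quartile factors. The trichome list had 0 and 1 called up and down adjusted over the list alone too, a median log2 of −0.092. Camera on trichome markers gave adjusted p = 0.493, or adjusted p = 0.692 with an estimated correlation. Flowering and floral organ markers had 1 higher, 1 lower and 7 not called of 9 tested members (1 and 1 adjusted over the list alone). Camera on flowering markers gave adjusted p = 0.975, or adjusted p = 0.982 with an estimated correlation. Their median log2 of 0.099 turned to −0.020 with upper-quartile factors, against a mean of −0.18 and a test pointing down. AG (AT4G18960, log2 −2.95, SE 0.23, adjusted p = 3.75e-06), a floral organ identity factor, fell and AGL8 (also FUL, AT5G60910, log2 1.13) rose, while SEP3 (AT1G24260, log2 0.64, adjusted p = 0.160) and SEP1 (AT5G15800, log2 0.37, adjusted p = 0.283) were not called. The root cell markers did not pass the filter on low counts. In cell division, edgeR called 0 of 9 tested genes (0 adjusted over the list alone and 0 at an unadjusted p under 0.05; 0 by DESeq2 and 0 by limma-voom), with a median log2 of −0.13. Camera on cell division gave adjusted p = 0.754, or adjusted p = 0.914 with an estimated correlation. Its members with the smallest adjusted p were CYCD3;1 (AT4G34160, log2 −0.31, adjusted p = 0.123), CYC1BAT (AT5G06150, log2 −0.21, adjusted p = 0.251), CYCB2;1 (AT2G17620, log2 0.23, adjusted p = 0.441) and SYP111 (also KNOLLE, AT1G08560, log2 −0.13, adjusted p = 0.493). CYCD3;1 passed without pdx3-4 2 (adjusted p = 0.0469) or with upper-quartile factors (0.0456), AGL8 was lost without wild type 2 (0.0504) and STM without wild type 1 or 2 (0.0689 and 0.0678).

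The remaining lists did not pass camera, while fry passed leaf senescence and auxin response (adjusted p = 0.00691 and 0.0148). Leaf senescence had 4 higher, 1 lower and 8 not called of 13 tested members (4 and 1 adjusted over the list alone), a median log2 of 0.14. Camera on leaf senescence gave adjusted p = 0.232, or adjusted p = 0.692 with an estimated correlation. BCB (also SAG14, AT5G20230, log2 3.51, SE 0.23, adjusted p = 1.10e-06), SAG21 (AT4G02380, log2 2.86), WRKY6 (AT1G62300, log2 1.8) and SEN1 (AT4G35770, log2 1.37) rose, of which the copper protein gene BCB and WRKY6 are also known from defence. Heat shock had 2 higher, 1 lower and 2 not called of 5 tested members (2 and 1 adjusted over the list alone), a median log2 of 0.27 and camera adjusted p = 0.493, or adjusted p = 0.692 with an estimated correlation, with HSP90.1 (AT5G52640, log2 0.78) and HSFA2 (AT2G26150, log2 1.31) higher, HSP101 (AT1G74310, log2 −0.42) lower and HSP70 (AT3G12580, log2 0.27, adjusted p = 0.133) not called. Cold and abscisic acid genes had 3 higher, 1 lower and 6 not called of 10 tested members (4 and 1 adjusted over the list alone), a median log2 of 0.87. Camera on cold and abscisic acid genes gave adjusted p = 0.395, or adjusted p = 0.692 with an estimated correlation. The protective protein genes COR47 (AT1G20440, log2 0.96, SE 0.13, adjusted p = 0.000188) and COR15B (AT2G42530, log2 0.79) rose, and of the near-identical regulators, whose counts are uncertain, CBF2 (AT4G25470, log2 3.09) rose and DREB1A (also CBF3, AT4G25480, log2 −1.97) fell. In auxin response, with 3 higher, 6 lower and 2 not called of 11 tested members (3 and 6 adjusted over the list alone), a median log2 of −0.63 and camera adjusted p = 0.212, or adjusted p = 0.510 with an estimated correlation, the synthesis gene YUC2 (AT4G13260, log2 −2.28) and SAUR15 (AT4G38850, log2 −1.31) fell while the repressors IAA6 (AT1G52830, log2 1.52) and IAA19 (AT3G15540, log2 0.71) rose. Iron deficiency and storage had 2 higher, 2 lower and 6 not called of 10 tested members (2 and 2 adjusted over the list alone), a median log2 of −0.23. Camera on iron deficiency and storage gave adjusted p = 0.838, or adjusted p = 0.872 with an estimated correlation. NAS4 (AT1G56430, log2 −1.20, SE 0.17, adjusted p = 0.000243), nicotianamine synthase, and the ferritin FER1 (AT5G01600, log2 −0.99) fell, and BTS (AT3G18290, log2 0.47), a ubiquitin ligase, and FRO3 (AT1G23020, log2 0.27), a ferric reductase, rose. For phosphate starvation, edgeR called 0 of 5 genes (0 adjusted over the list alone and 0 at an unadjusted p under 0.05; 0 by DESeq2 and by limma-voom), with a median log2 of −0.15. Camera on phosphate starvation gave adjusted p = 0.584, or adjusted p = 0.813 with an estimated correlation. Log2 was −0.15 for SQD2 (AT5G01220, adjusted p = 0.183), −0.53 for PHT1;4 (AT2G38940, 0.205), −0.46 for PAP17 (AT3G17790, 0.321) and −0.021 for SPX1 (AT5G20150, 0.899), which turned to 0.033 with library size alone. In the single alleles SPX1 was called in opposite directions, at log2 0.55 in pdx3-3 and −0.59 in pdx3-4 (adjusted p = 0.00622 and 0.00494). Calls changed for HSP101 without wild type 1 (adjusted p = 0.0796), for FER1 without wild type 1 (log2 −0.46, 0.218) or pdx3-4 3 (0.0600), for SQD2 without wild type 3 (0.0375) or with upper-quartile factors (0.0129) and for PAP17 without pdx3-4 1 (0.0319). FRO3 was lost when any single library other than pdx3-3 2 or pdx3-4 3 was left out (0.0563 to 0.1105) and with upper-quartile factors (0.223), and FER1 with robust quasi-likelihood (0.0695).

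**Figure D3:**
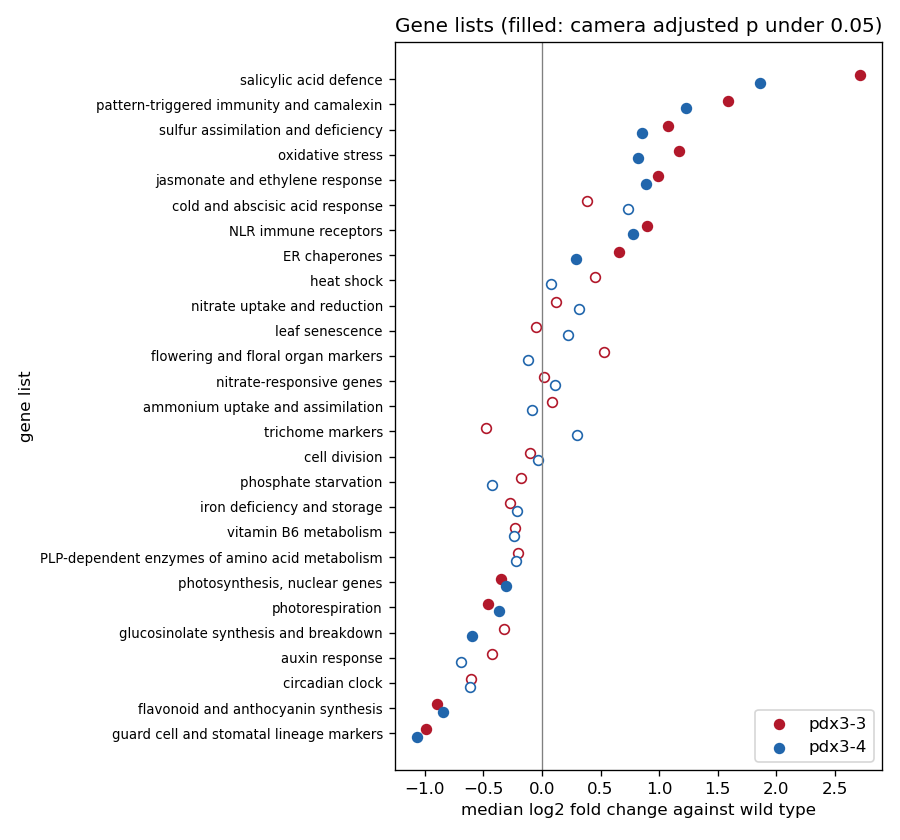
Median log2 fold change against wild type (horizontal axis) of each tested gene list (vertical axis) in pdx3-3 and pdx3-4, with filled points where camera's adjusted p was under 0.05. The salicylic acid defence list lies farthest to the right (2.71 in pdx3-3 and 1.87 in pdx3-4) and the guard cell list farthest to the left (−0.99 and −1.07).

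Over all genes, 4085 were higher and 4049 lower in the mutants (43.3% of 18783 tested, 1598 and 463 of them by at least 2-fold). Of 27 lists tested, 12 passed camera, 7 upward and 5 downward, and 18 passed fry; with an estimated correlation camera passed 0, with 4 at an unadjusted p under 0.05. For the genes called from the lists, all 6 mutant libraries lay beyond every wild-type library, except PDX1.2 (4 of 6), HSFA2, FRO3, AGL8, STM and SUC2 (5 of 6 each) and FER1 (3 of 6). As genes were named from the lists by their small adjusted p in this comparison, that separation is no separate evidence. Over all tested genes, mutant and wild-type libraries did not overlap for 36.6%. Of the named genes called, PDX1.2, HSP90.1, HSFA2, FER1, AGL8, KNAT1 and STM were not called in pdx3-4 (adjusted p = 0.0511 to 0.541) and FRO3 was not called in pdx3-3 (adjusted p = 0.1775), while only PDX1.2 and KNAT1 among them differed between the alleles (adjusted p = 0.0196 and 0.0116). With upper-quartile factors the median of all genes moved by −0.12 and the share of higher calls from 50.2% to 33.6%, but no list or named gene past the threshold changed direction under any scaling.

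Set against wild type, pdx3-3, the line with the lower PDX3 level, had defence and ER chaperone genes higher and nuclear photosynthesis genes lower, beside large changes of single genes. XTH18 (AT4G30280, log2 6.47, SE 0.39, adjusted p = 8.09e-07), a cell wall xyloglucan enzyme, rose from 1.39 ± 0.533 CPM in wild type to 123 ± 51.1, and ACS7 (AT4G26200, log2 6.29, SE 0.37, adjusted p = 6.78e-07), an enzyme of ethylene synthesis, from 0.0867 ± 0.0624 to 7.13 ± 1.57. RRTF1 (AT4G34410, log2 6.61, SE 1.45, adjusted p = 0.00470), an ERF transcription factor, had 17.0 ± 17 CPM against 0.173 ± 0.222, and limma-voom did not call it (adjusted p = 0.226). AT3G60470 (log2 6.95, SE 0.36, adjusted p = 4.48e-07), the pseudogene AT5G35935 (log2 6.70) and AT2G44240 (log2 6.24, SE 1.69, adjusted p = 0.0144) completed the 6 largest rises named by the rule for genes with no overlap of libraries. AT3G60470 had 3 counts over all wild-type libraries and 410 in pdx3-3, a ratio of 138 (exact 95% interval 46.9 to 672, counting error only). On the lower side, MRD1 (AT1G53480, log2 −5.71, SE 0.17, adjusted p = 5.77e-08) on chromosome 1, 19963047 to 19964712 fell from 19.3 ± 1.61 CPM in wild type to 0.365 ± 0.0803, followed by AT3G09450 (log2 −3.56), PDX3, AT1G20070 (log2 −2.76), the auxin-induced gene SAUR20 (AT5G18020, log2 −2.61, SE 0.23, adjusted p = 8.26e-06) and GER3 (AT5G20630, log2 −2.52, SE 0.23, adjusted p = 1.09e-05), a germin-like protein gene that dropped from 91.1 ± 27.1 to 15.8 ± 3.88 CPM. Salicylic acid defence rose in 28 of 33 genes (29 adjusted over the list alone), at a median log2 of 2.71 with camera adjusted p = 8.75e-16, or adjusted p = 0.208 with an estimated correlation, and ER chaperones rose in 8 of 8 (0.66, camera adjusted p = 1.36e-05, or adjusted p = 0.309 with an estimated correlation). Nuclear photosynthesis genes fell in 31 of 32 (31 adjusted over the list alone, median log2 −0.35). Camera on nuclear photosynthesis genes gave adjusted p = 7.11e-10, or adjusted p = 0.320 with an estimated correlation. In all, 3562 genes were higher and 3284 lower, 1646 and 493 by at least 2-fold (36.45% of genes called), and 41 organellar or ribosomal RNA genes were among the higher ones. Libraries of the 2 groups did not overlap for 47.4% of genes, where chance gives 10%. Of 27 lists, 11 passed camera (7 up, 4 down), with adjusted p = 0.208 to 0.330 for them with an estimated correlation, and median, mean and test differed in sign for nitrate uptake, PLP-dependent enzymes, leaf senescence, iron and phosphate starvation. The AT2G44240 call was lost without wild type 2 (adjusted p = 0.0525) or pdx3-3 2 (log2 4.21, 0.0649), by limma-voom (0.149) and with robust quasi-likelihood (0.05325). The glucosinolate list, at −0.33 and adjusted p = 0.229, passed without wild type 2 (0.04955). Upper-quartile factors lowered the share of higher calls from 52.0% to 34.1%, library size alone raised it to 62.1%, and with pdx3-3 libraries 1 and 2 both left out, a check chosen after seeing the data that leaves 1 pdx3-3 library, 1449 genes were lower.

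In pdx3-4, which retained more PDX3 transcript, defence genes rose and nuclear photosynthesis and guard cell genes fell. The 6 largest rises named by the rule were AT5G39580 (log2 6.98, SE 0.62, adjusted p = 1.13e-05), a peroxidase, from 0.0674 ± 0.0248 CPM in wild type to 9.43 ± 2.34, ACS7 (log2 6.06, SE 0.37, adjusted p = 1.49e-06), PHI-1 (log2 6.0, SE 0.33, adjusted p = 7.95e-07), XTH33 (AT1G10550, log2 5.82), JAZ7 (log2 5.56) and XTH18 (log2 5.56). PHI-1 reached 557 ± 73.7 CPM from 8.71 ± 1.56 in wild type. Among the largest falls were AT2G15020 (log2 −3.72, SE 0.20, adjusted p = 7.95e-07), from 92.5 ± 20.6 to 6.99 ± 1.81 CPM, AT3G09450 (log2 −3.61), AT2G27420 (log2 −3.28), the pseudogene AT3G15310 (log2 −3.22), the xyloglucan enzyme gene XTH31 (AT3G44990, log2 −3.12, SE 0.38, adjusted p = 8.83e-05) and AT5G66740 (log2 −2.91). Salicylic acid defence had 24 higher and 1 lower of 33 (26 and 1 adjusted over the list alone), median log2 1.87. Camera on salicylic acid defence gave adjusted p = 7.42e-10, or adjusted p = 0.386 with an estimated correlation. Nuclear photosynthesis had 0 higher and 25 lower of 32 (0 and 29 adjusted over the list alone), median log2 −0.30. Camera on nuclear photosynthesis genes gave adjusted p = 2.92e-08, or adjusted p = 0.463 with an estimated correlation. Glucosinolate genes had 1 higher and 11 lower of 20 (1 and 12 adjusted over the list alone), median log2 −0.60. Camera on glucosinolate genes gave adjusted p = 0.00113, or adjusted p = 0.544 with an estimated correlation. Guard cell markers fell in 6 of 6 (−1.07, camera adjusted p = 0.000237, or adjusted p = 0.386 with an estimated correlation). ER chaperones rose in 6 of 8 (6 adjusted over the list alone, median log2 0.29). Camera on ER chaperones gave adjusted p = 0.00979, or adjusted p = 0.512 with an estimated correlation. Counts of called genes were 3921 higher and 3448 lower, 1512 and 471 by at least 2-fold (39.2% of genes), and the 2 groups' libraries did not overlap for 49.7% of genes against 10% by chance. Camera passed 12 of 27 lists (7 up, 5 down; adjusted p = 0.386 to 0.544 for them with an estimated correlation), and signs differed between median, mean and test for ammonium uptake and trichome markers. The PLP-dependent list, at −0.22 and adjusted p = 0.0580, passed without wild type 3 (0.0304) or pdx3-4 1 (0.0404), with library size alone (0.0492) and with no filter (0.0413). In a check chosen after seeing the data, ER chaperones were lost with wild type 1 and pdx3-4 1 both left out (0.0615). Upper-quartile factors lowered the share of higher calls from 53.2% to 36.8%.

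The alleles shared most of their calls. Of the genes called against wild type, 2923 were higher and 2481 lower in both alleles, against 743.6 and 602.8 for independent lists of those sizes and 0 in 20 simulations of unchanged groups set against shared wild-type libraries, which called too few genes for any to be shared. The log2 fold changes of the alleles correlated across genes at 0.875 (simulated 0.505, range 0.480 to 0.528; genes are not independent replicates), and their covariance was 0.573 against a simulated 0.0224, a difference of 0.551. Signs matched for 84.6% of genes, against 66.9% in simulations. The 3 wild-type libraries could not be split into parts of at least 2, so part of the excess in shared calls, correlation and matching signs can come from the shared controls, while the difference of covariances has their simulated part taken off. Called in opposite directions were 9 genes, singled out after their values were seen: higher in pdx3-3 and lower in pdx3-4 were the phosphate sensor SPX1 (log2 0.55 and −0.59), the ubiquitin ligase PUB29 (AT3G18710, 0.79 and −0.90), AT3G14200, AT4G02410 and AT5G14700, and the reverse held for the gibberellin-regulated GASA1 (AT1G75750, −0.94 and 0.59), PKS2 (AT1G14280, −0.46 and 0.42), C/VIF2 (AT5G64620, −0.28 and 0.33) and AT1G56720.

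Set directly against each other, the alleles differed in defence genes and in other lists. Salicylic acid defence was higher in pdx3-3 than in pdx3-4 in 16 of 33 genes and lower in 0 (20 and 0 adjusted over the list alone), at a median log2 difference of 0.79 with camera adjusted p = 5.24e-13, or adjusted p = 0.473 with an estimated correlation. PBS3 had CPM of 6.78 ± 0.818 in wild type, 50.4 ± 0.889 in pdx3-3 and 25.6 ± 2.64 in pdx3-4, and SARD1 had CPM of 6.61 ± 1.41 in wild type, 135 ± 32.2 in pdx3-3 and 54.1 ± 4.68 in pdx3-4. Pattern-triggered immunity had 6 higher and 1 lower of 23 (6 and 1 adjusted over the list alone), median log2 0.54. Camera on pattern-triggered immunity gave adjusted p = 0.00194, or adjusted p = 0.485 with an estimated correlation. NLR receptors had 2 higher and 0 lower of 16 (6 and 0 adjusted over the list alone), median log2 0.22. Camera on NLR immune receptors gave adjusted p = 0.00375, or adjusted p = 0.656 with an estimated correlation. ER chaperones were higher in 7 of 8 (8 adjusted over the list alone; 0.40, camera adjusted p = 1.19e-06, or adjusted p = 0.473 with an estimated correlation). The oxidative stress list had 7 higher and 0 lower of 15 (8 and 0 adjusted over the list alone), median log2 0.35. Camera on oxidative stress gave adjusted p = 2.24e-05, or adjusted p = 0.473 with an estimated correlation. Its member BCS1 was at 267 ± 52.7 CPM in pdx3-3 and 70.4 ± 2.89 in pdx3-4. Glucosinolate genes had 5 higher and 2 lower of 20 (10 and 2 adjusted over the list alone), median log2 0.51. Camera on glucosinolate genes gave adjusted p = 0.000373, or adjusted p = 0.656 with an estimated correlation. MYB51 was at 144 ± 30.9 and 51.2 ± 0.851 CPM. The PLP-dependent list had 3 higher and 0 lower of 34 (3 and 0 adjusted over the list alone), median log2 0.065. Camera on PLP-dependent enzymes gave adjusted p = 0.0258, or adjusted p = 0.485 with an estimated correlation. Flowering markers had 1 higher and 0 lower of 9 (2 and 0 adjusted over the list alone), median log2 0.98. Camera on flowering markers gave adjusted p = 0.0453, or adjusted p = 0.485 with an estimated correlation. Nitrate-responsive genes, the list lower in pdx3-3, had 0 higher and 3 lower of 16 (1 and 5 adjusted over the list alone), median log2 −0.21. Camera on nitrate-responsive genes gave adjusted p = 0.0493, or adjusted p = 0.656 with an estimated correlation.

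**Figure D4:**
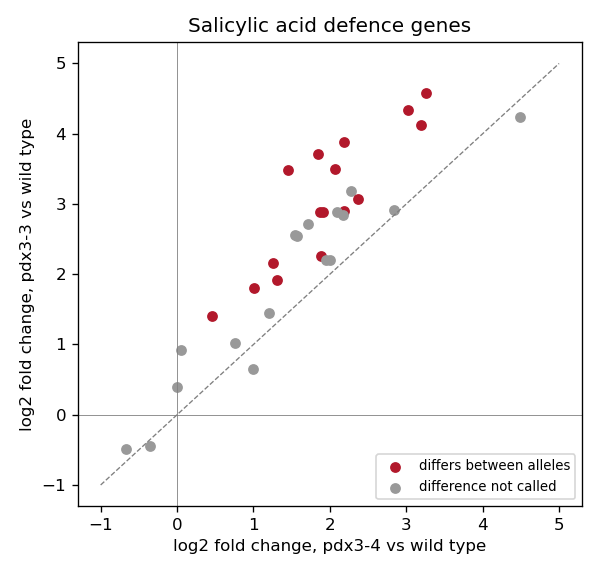
Log2 fold change against wild type of 33 salicylic acid defence genes in pdx3-4 (horizontal axis) and pdx3-3 (vertical axis), from 3 libraries per genotype, with the line of equality dashed. The 16 genes that differ between the alleles all lie above the line.

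Of single genes, the pseudogene AT5G35935 (log2 8.23, SE 0.41, adjusted p = 8.01e-06) on chromosome 5, 14083388 to 14089891 stood at 11.3 ± 0.526 CPM in pdx3-3, 0.0316 ± 0.0274 in pdx3-4 and 0.103 ± 0.106 in wild type. It had 651 counts over the pdx3-3 libraries and 2 in pdx3-4, a ratio of 358 (exact 95% interval 98.6 to 2959, counting error only). MRD1 was near absent in pdx3-3 (log2 −5.95, adjusted p = 4.04e-08) and at 22.8 ± 2.19 CPM in pdx3-4. After PDX3, SOB5 (AT5G08150, log2 −2.03, SE 0.20, adjusted p = 0.000431), the cytokinin response regulator ARR6 (AT5G62920, log2 −1.70, SE 0.32, adjusted p = 0.0124), AT5G11330 (log2 −1.57) and the anthocyanin synthesis gene DFR (AT5G42800, log2 −1.53, SE 0.31, adjusted p = 0.0178) were lower in pdx3-3. Next in size on the higher side were an rRNA gene, AT3G41768 (log2 4.77), and the chloroplast genes ATCG00020 (psbA, 4.89), ATCG00490 (rbcL, 4.76), ATCG00580 (psbE, 4.60) and ATCG00350 (psaA, 4.45), with adjusted p = 0.0221 to 0.0278. These were carried by pdx3-3 libraries 1 and 2: without both, which leaves 1 pdx3-3 library, their log2 differences were 0.54 to 1.18. None of them passed with limma-voom (0.0593 to 0.342) or robust quasi-likelihood (0.0997 to 0.117). In the whole comparison 624 genes were higher and 533 lower (6.16% of genes, 267 and 49 by at least 2-fold), and 29 of the higher ones were organellar or ribosomal RNA genes. Libraries did not overlap for 28.45% of genes, against 10% by chance. Camera passed 9 of 27 lists (8 up, 1 down) and fry 4, among them vitamin B6 (0.0414, or 0.903 without PDX3), and of the 9 those of pattern-triggered immunity, NLR receptors, glucosinolates, PLP-dependent enzymes, flowering and nitrate response were lost with fry (0.0989 to 0.267). No member was called by edgeR in photorespiration, heat shock, auxin response, iron, cell division, guard cell or trichome lists, with 1, 3, 2, 1, 0, 0 and 1 members at an unadjusted p under 0.05, 1 heat shock gene called by DESeq2 and 0 genes by limma-voom. Adjusted over the list alone, 1 heat shock and 1 iron gene were higher in pdx3-3 and 0 in the other lists named.

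These counts moved with single libraries. Without pdx3-4 3 the alleles differed in 246 higher and 145 lower genes, without wild type 3 in 990 and 826, without pdx3-3 2 in 297 and 224, and without pdx3-4 2 in 293 and 306. The number lower was 297 without pdx3-3 1, 352 without pdx3-3 3 and 345 without pdx3-4 1. The nitrate-responsive call was lost without wild type 1 or 2, pdx3-3 1 or 2 or pdx3-4 2 (adjusted p = 0.0542, 0.0552, 0.0561, 0.0739 and 0.08955), and with every other scaling (0.0520 to 0.0569), the PLP-dependent call without pdx3-3 1 (0.0561) or pdx3-4 2 (0.103), the NLR call without pdx3-3 3 (0.0780), and the flowering call without pdx3-3 2 (0.0682), pdx3-3 3 (0.173) or pdx3-4 2 (0.0841) and with median-of-ratios factors (0.0552). Only the groups compared in the fit also ended the nitrate-responsive and flowering calls (0.0548 and 0.0813). Lists that passed with a library left out were nitrate uptake (pdx3-3 1, 0.0396, or pdx3-4 3, 0.0306), jasmonate and ethylene (pdx3-3 3, 0.0405, or pdx3-4 1, 0.0296), photosynthesis (pdx3-3 1, 0.0289, or pdx3-4 1, 0.0296), flavonoids (pdx3-3 2, 0.0425) and heat shock (pdx3-3 2, 0.0425). The DFR call was lost without pdx3-4 2 (adjusted p = 0.0639) or pdx3-4 3 (0.0569), and the organellar and ribosomal calls without any of the pdx3-4 libraries (0.0784 to 0.121), with ATCG00020, ATCG00580 and ATCG00350 also lost without pdx3-3 1 or 2 (0.0506 to 0.0640).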

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

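The tests of RNA carried over into pdx3-3 libraries, of a common scale, of harvest hour and of close gene neighbours were chosen after their results were seen, while the splits of libraries and the plain tests for a chromosome segment were chosen before. Allele differences below come from a direct test between the alleles, by which 1157 genes differed. With only the libraries compared fitted, the real grouping called 5891 genes for pdx3-3 against wild type, 6732 for pdx3-4 against wild type and 1612 between the alleles, where the highest other of 10 splits gave 0, 0 and 3. Only 1 of the 10, the real one, reached these counts, but 10 splits are too few for a share under 0.05. For both alleles against wild type, 1 of 84 splits, the real one, reached 7442, a share under 0.05, the highest other giving 123. Every other split put wild-type and mutant libraries into a shared group, so a genotype effect adds to their spread. The splits therefore do not exclude chance, and cannot tell genotype from a difference in how the lines were grown.

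The salicylic acid defence list was higher in pdx3-3 by a median log2 of 0.79 (camera adjusted p = 5.24e-13, or adjusted p = 0.473 with an estimated correlation). A stronger loss of PDX3 that scales every response alike is argued against as the whole difference between the alleles. Of 650 nuclear genes called in all 3 tests and the same way in both alleles, PDX3 among them, 42.8% (exact 95% interval 38.9 to 46.7) changed more in pdx3-4. The share was 39.0% (34.9 to 43.2) of the 559 higher and 65.9% (55.25 to 75.55) of the 91 lower ones. These intervals treat genes as independent, which they are not, and so are too narrow. Genes that changed more in pdx3-4 could also come from a difference in how the lines were grown. An effect of RNA carried over from organelles and ribosomes into pdx3-3 libraries 1 and 2 cannot be told apart, because leaving them out leaves 1 pdx3-3 library, with a median of 0.72. With organellar and ribosomal RNA genes left out of the fit, the list still passed camera at the fixed correlation. That check does not cover other ways in which these libraries may differ. A difference between the alleles themselves stays open, as it is confounded with any difference in how the lines were grown.

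Of the tested clock genes, all but PRR7 were called, morning genes lower and evening genes higher in both mutants. PRR7 was left out of the score, so the score holds no gene that goes against this split. The evening minus morning score was −3.31 ± 0.14 in wild type, −1.54 ± 0.14 in pdx3-3 and −1.53 ± 0.16 in pdx3-4. Between the alleles the clock difference was 0.994 times as large in pdx3-3 as in pdx3-4 and the defence median 1.46 times, but members went both ways, such as LHY (log2 −0.28, adjusted p = 0.0449) and PRR9 (AT2G46790, log2 0.75, adjusted p = 0.0248), chosen after their values were seen. The near-equal scores of the alleles count against a later harvest hour as the whole cause of the allele difference in defence genes. It still cannot be told apart, because single members went both ways. The members' median shortfall from the clock change it needs was 0.24, with an SD of 0.42. That SD is the spread among genes and not the error of the median. As part of the change against wild type, a later harvest hour cannot be told apart from genotype. In a score built from genes already called, 6 of 6 mutant libraries lay above every wild-type library. No source used here gives the hour.

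Some genes were present in 1 allele and nearly absent in the other: AT5G35935 (log2 8.23), MRD1 (−5.95) and, chosen after its values were seen, AT1G27565 with 37, 29 and 34 counts in pdx3-3 and 0 in every other library. A chromosome segment of another origin that reaches up to 1 Mb from PDX3 is argued against as the source of these 3 genes, as 0 of them lie there. Of 286 nuclear genes called at 2-fold between the alleles, PDX3 left out, 5 lay within 1 Mb of PDX3 (95% of 10000 draws held at most 9, permutation p = 0.590). A longer segment was not tested, and AT5G35935 lies on the chromosome of PDX3, with starts at 14083388 and 20329103. A segment elsewhere cannot be told apart, because the densest 500 kb window, on chromosome 1, held 10 such genes (95% of draws 8, permutation p = 0.0047) but 0 of these 3, so it does not bear on them. Nor does the count of 5 with neighbours within 20 kb counted once. A 500 kb window centred on each of the 3 held 4 other such genes for MRD1, 1 for AT1G27565 and 0 for AT5G35935. These counts were not set against draws.

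By camera at a fixed correlation, other lists differed by median log2 differences of 0.54 for pattern-triggered immunity and camalexin, 0.22 for NLR immune receptors, 0.40 for ER chaperones, 0.51 for glucosinolates, 0.35 for oxidative stress, 0.98 for flowering markers, 0.065 for PLP-dependent enzymes and −0.21 for nitrate-responsive genes. None of them passed with an estimated correlation (adjusted p = 0.473 to 0.656), and all but ER chaperones and oxidative stress were lost with fry (adjusted p = 0.0989 to 0.267). Among single genes, PDX1.2 differed by 0.64, PDX3 by −2.29, AT3G60470 by 1.36, GER3 by −0.99, XTH33 by −1.41, AT2G15020 by 1.29, AT3G15310 by 1.92, XTH31 by 1.66, SOB5 by −2.03, ARR6 by −1.70, AT5G11330 by −1.57 and DFR by −1.53. Organellar and ribosomal RNA genes differed by 4.89 for ATCG00020, 4.77 for AT3G41768, 4.76 for ATCG00490, 4.60 for ATCG00580 and 4.45 for ATCG00350.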

How the results depend on the processing

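The joint removals of libraries and of organellar with ribosomal RNA genes, and the vitamin B6 list without PDX3, were chosen after the data were seen, and all other alternatives before. Of 166 results for named genes, 142 past the threshold, 130 kept their direction and side of the threshold in every alternative that gave a value. DESeq2 gave no adjusted p for AT2G44240. No gene or list past the threshold changed direction, and the cause of changes was not tested except where fewer libraries or a stricter threshold entered. Upper-quartile factors raised the numbers lower to 5553 in pdx3-3, 5317 in pdx3-4, 6367 for both alleles and 4265 shared. At an adjusted p under 0.01, numbers lower were 1884, 2031 and 2568 for pdx3-3, pdx3-4 and both alleles, 1388 shared, and 237 higher and 132 lower between alleles. At 2-fold or more, counts higher and lower were 1646 and 493 in pdx3-3, 1512 and 471 in pdx3-4, 267 and 49 between alleles, 1598 and 463 for both alleles, and 1218 and 275 shared. Leaving out pdx3-3 1 and 2 leaves 1 pdx3-3 library, with the spread taken from the other groups, so its values and adjusted p here and below show no group change. Without them, counts were 1449 lower in pdx3-3, 318 higher and 40 lower between alleles and 1325 shared lower. Without wild type 1 and pdx3-4 1, they were 2142 lower in pdx3-4, 415 higher and 299 lower between alleles and 1561 shared lower. Leaving out each library in turn gave 246 to 990 genes higher and 145 to 826 lower between alleles. With an estimated correlation camera passed 0 lists in each of the 4 comparisons, with 6, 2, 2 and 4 at an unadjusted p under 0.05 for pdx3-3, pdx3-4, between alleles and both alleles, while fry passed 16, 21, 4 and 18.

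Replicate numbers were not shown to pair the libraries: same-number correlations ran from −0.1503 to 0.343, 2 of 9 pairs were over 0.1, and 3 of 9 libraries correlated best with their own number. With the replicate number as a block, counts higher and lower were 3447 and 3023 in pdx3-3, 3739 and 3179 in pdx3-4, 606 and 483 between alleles, 3971 and 3775 for both alleles, and 2804 and 2267 shared. Lists past were 11, 12, 11 and 12. The block gained nitrate uptake (adjusted p = 0.0457) and heat shock (0.0310) between alleles, lost PDX1.1 and PLR1 in pdx3-4 (0.0546 and 0.0586) and FRO3 for both alleles (0.0687), and changed no other call.

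Signs of uncalled medians and genes changed as follows. With upper-quartile factors, values were nitrate uptake and reduction −0.00074, nitrate-responsive genes −0.11 and ammonium uptake and assimilation −0.046 in pdx3-3. In pdx3-4, they were nitrate-responsive genes −0.0090, heat shock −0.042 and SOS4 −0.11. For both alleles, they were nitrate-responsive genes −0.076, flowering and floral organ markers −0.020 and GL2 −0.023. Between alleles, they were PLR1 −0.0031. With pdx3-3 libraries 1 and 2 both left out, values were nitrate uptake and reduction −0.15, nitrate-responsive genes −0.041 and leaf senescence 0.043 in pdx3-3. Between alleles, they were jasmonate and ethylene response −0.092, iron deficiency and storage −0.27, phosphate starvation −0.11, guard cell and stomatal lineage markers −0.063 and PLR1 −0.026. For both alleles, they were ammonium uptake and assimilation 0.0073 and SPX1 0.063. With wild type 1 and pdx3-4 1 both left out, values were nitrate-responsive genes −0.016, iron deficiency and storage 0.071 and phosphate starvation 0.32 in pdx3-3. Between alleles, they were leaf senescence 0.013, PDX2 0.029 and PLR1 −0.036. For both alleles, they were iron deficiency and storage 0.098, phosphate starvation 0.031, flowering and floral organ markers −0.18, trichome markers 0.095, PHT1;4 0.068, SPX1 0.031 and MYB0 0.095. In pdx3-4, they were SOS4 −0.029. With library size alone, values were leaf senescence 0.0077 and PDX2 0.0069 in pdx3-3. In pdx3-4, they were cell division 0.016 and PDX2 0.017. For both alleles, they were ammonium uptake and assimilation 0.038 and SPX1 0.033. With the filter at 1 CPM in 3 libraries, values were leaf senescence 0.0051 in pdx3-3. Between alleles, they were flavonoid and anthocyanin synthesis 0.032 and iron deficiency and storage −0.051. For both alleles, they were ammonium uptake and assimilation 0.028. With no filter, values were circadian clock 0.075 in pdx3-3. In pdx3-4, they were circadian clock 0.11. Between alleles, they were flavonoid and anthocyanin synthesis 0.048. For both alleles, they were ammonium uptake and assimilation 0.023, circadian clock 0.092 and flowering and floral organ markers −0.055. Under the setting of only the groups compared, values were flavonoid and anthocyanin synthesis 0.041 and iron deficiency and storage −0.021 between alleles. With each library left out, results that changed sign somewhere had these log2 ranges. In pdx3-3, ranges were nitrate uptake and reduction −0.18 to 0.22, nitrate-responsive genes −0.037 to 0.050, ammonium uptake and assimilation −0.011 to 0.12, leaf senescence −0.051 to 0.024, iron deficiency and storage −0.39 to 0.12, phosphate starvation −0.39 to 0.33 and cell division −0.23 to 0.14. In pdx3-4, ranges were leaf senescence −0.078 to 1.40, heat shock −0.011 to 0.18, cell division −0.18 to 0.20, trichome markers −0.031 to 0.51, PDX2, pdx3-4 vs wild type, −0.097 to 0.0075 and SOS4 −0.0094 to 0.045. Between alleles, ranges were flavonoid and anthocyanin synthesis −0.27 to 0.14, leaf senescence −0.21 to 0.013, iron deficiency and storage −0.00039 to 0.15, phosphate starvation −0.13 to 0.61, cell division −0.17 to 0.011, guard cell and stomatal lineage markers −0.013 to 0.14, PDX2 −0.057 to 0.029 and PLR1 −0.036 to 0.023. For both alleles, ranges were ammonium uptake and assimilation −0.093 to 0.048, iron deficiency and storage −0.29 to 0.11, phosphate starvation −0.32 to 0.067, cell division −0.26 to 0.15, flowering and floral organ markers −0.18 to 0.49, trichome markers −0.38 to 0.12, PHT1;4 −0.80 to 0.067, SPX1 −0.13 to 0.086, CYC1BAT −0.35 to 0.038, SYP111 −0.28 to 0.10, MYB0 −0.38 to 0.12 and GL2 −0.27 to 0.50.

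With pdx3-3 libraries 1 and 2 both left out, these calls were lost (adjusted p in brackets): nitrate-responsive genes, pdx3-3 vs pdx3-4 (0.186), PLP-dependent enzymes of amino acid metabolism, pdx3-3 vs pdx3-4 (0.233), glucosinolate synthesis and breakdown, pdx3-3 vs pdx3-4 (0.116), PDX1.1, pdx3-4 vs wild type (0.0639), PLR1, pdx3-4 vs wild type (0.0896), PDX1.2, pdx3-3 vs pdx3-4 (0.322), AT2G44240, pdx3-3 vs wild type (0.118), ATCG00020, pdx3-3 vs pdx3-4 (0.812), AT3G41768, pdx3-3 vs pdx3-4 (0.816), ATCG00490, pdx3-3 vs pdx3-4 (0.799), ATCG00580, pdx3-3 vs pdx3-4 (0.706), ATCG00350, pdx3-3 vs pdx3-4 (0.874), ARR6, pdx3-3 vs pdx3-4 (0.1745), PDX1.2, both alleles vs wild type (0.0669) and HSP101, both alleles vs wild type (0.0804). The same removal gained glucosinolate synthesis and breakdown, pdx3-3 vs wild type (0.0402) and flavonoid and anthocyanin synthesis, pdx3-3 vs pdx3-4 (2.005e-06). With wild type 1 and pdx3-4 1 both left out, these calls were lost (adjusted p in brackets): ER chaperones, pdx3-4 vs wild type (0.0615), PDX1.1, pdx3-4 vs wild type (0.0838), PLR1, pdx3-4 vs wild type (0.277), PDX1.2, pdx3-3 vs pdx3-4 (0.0553), ATCG00020, pdx3-3 vs pdx3-4 (0.0751), AT3G41768, pdx3-3 vs pdx3-4 (0.0768), ATCG00490, pdx3-3 vs pdx3-4 (0.0768), ATCG00580, pdx3-3 vs pdx3-4 (0.0897), ATCG00350, pdx3-3 vs pdx3-4 (0.104), DFR, pdx3-3 vs pdx3-4 (0.0574), HSFA2, both alleles vs wild type (0.0595), HSP101, both alleles vs wild type (0.101), FER1, both alleles vs wild type (0.275), FRO3, both alleles vs wild type (0.175) and STM, both alleles vs wild type (0.0669). The same removal gained jasmonate and ethylene response, pdx3-3 vs pdx3-4 (0.0379), photosynthesis, nuclear genes, pdx3-3 vs pdx3-4 (0.0379) and phosphate starvation, pdx3-3 vs pdx3-4 (0.0379). As it kept the pdx3-3 library with the highest PR1 level, the removal was uneven between the alleles. The filter at 1 CPM in 3 libraries lost nitrate-responsive genes, pdx3-3 vs pdx3-4 (0.0564) and flowering and floral organ markers, pdx3-3 vs pdx3-4 (0.0509). Leaving out organellar genes lost nitrate-responsive genes, pdx3-3 vs pdx3-4 (0.0507). Leaving out organellar and ribosomal RNA genes lost nitrate-responsive genes, pdx3-3 vs pdx3-4 (0.05355). Fitting only the groups compared lost nitrate-responsive genes, pdx3-3 vs pdx3-4 (0.0548), flowering and floral organ markers, pdx3-3 vs pdx3-4 (0.0813), PDX1.1, pdx3-4 vs wild type (0.0598) and PLR1, pdx3-4 vs wild type (0.0844) and gained PDX1.1, pdx3-3 vs pdx3-4 (0.0422).

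With this design, simulated changes of 1.5-fold were recovered at 50.8% for pdx3-3, 38.8% for pdx3-4 and 41.8% between alleles, so uncalled genes are not shown to be unchanged.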

Other observations

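The 116 families of genes with a shared symbol and at least 10 tested members were chosen after the data were seen, and examples of those past the camera threshold follow. A shared symbol can hold unrelated genes. For both alleles against wild type, CRK genes, mostly cysteine-rich receptor-like kinases, had 28 of 34 higher and 3 lower, median log2 1.45. Camera on CRK genes gave adjusted p = 1.01e-08, or adjusted p = 0.571 with an estimated correlation. WRKY factors, 11 of them also in the lists, had 29 of 46 higher and 3 lower, median log2 0.95. Camera on WRKY genes gave adjusted p = 6.13e-08, or adjusted p = 0.571 with an estimated correlation. Calcium-dependent protein kinases (CPK) had 12 of 19 higher and 0 lower, median log2 0.48. Camera on CPK genes gave adjusted p = 0.000228, or adjusted p = 0.571 with an estimated correlation. Plant U-box ligases (PUB) had 14 of 21 higher and 0 lower, median log2 0.56. Camera on PUB genes gave adjusted p = 0.00135, or adjusted p = 0.571 with an estimated correlation. Receptor-like proteins (RLP) had 24 of 48 higher and 4 lower, median log2 0.58. Camera on RLP genes gave adjusted p = 0.00157, or adjusted p = 0.613 with an estimated correlation. On the lower side, expansins (EXPA) had 0 of 13 higher and 10 lower, median log2 −0.61. Camera on EXPA genes gave adjusted p = 0.00292, or adjusted p = 0.571 with an estimated correlation. SAUR auxin genes had 0 of 15 higher and 9 lower, median log2 −0.81. Camera on SAUR genes gave adjusted p = 0.00844, or adjusted p = 0.578 with an estimated correlation. Ribosomal proteins (RPL) had 1 of 21 higher and 13 lower, median log2 −0.27. Camera on RPL genes gave adjusted p = 0.00844, or adjusted p = 0.700 with an estimated correlation. Between the alleles, higher meaning higher in pdx3-3, RLP genes had 6 of 48 higher and 0 lower, median log2 0.43. Camera on RLP genes gave adjusted p = 1.17e-05, or adjusted p = 0.757 with an estimated correlation. CRK genes had 8 of 34 higher and 0 lower, median log2 0.44. Camera on CRK genes gave adjusted p = 3.19e-05, or adjusted p = 0.757 with an estimated correlation. On the lower side, SAUR genes had 0 of 15 higher and 2 lower, median log2 −0.49. Camera on SAUR genes gave adjusted p = 3.19e-05, or adjusted p = 0.686 with an estimated correlation.

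PR1 (AT2G14610), a standard marker of salicylic acid defence chosen after its values were seen, had CPM of 35.7, 4.04 and 0.0534 in the wild-type libraries, 70.9, 159 and 30.04 in pdx3-3, and 69.0, 15.0 and 46.2 in pdx3-4. It was not called against wild type (log2 2.71, adjusted p = 0.0623 and log2 1.72, adjusted p = 0.213).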
